A study of Rattus norvegicus with 20 samples.

How the data were processed

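Total RNA from the lungs of 20 male CDF Fisher 344 rats (strain as labelled), an inbred laboratory strain, aged 3 months, was measured on Illumina rat bead arrays, 1 array per rat. Per the labels, 8 rats had inhaled crystalline silica and 12 had breathed air as controls. Biotin-labelled cRNA was made from 375 ng of RNA per sample. On such an array each probe sits on many beads, and the bead intensities are averaged.

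The deposited table of intensities, which has a mean bead intensity for each gene and array, was summarised with BeadStudio, per the submitters' processing notes. Its intensities were neither background-subtracted nor normalized, judging from the values. The same table holds detection p-values, deposited by the authors for every gene and array, and the number of beads behind each mean, also deposited by the authors. The authors' deposited log2 values are normalized between arrays: the array means ranged from 8.354 to 8.357, and the processing notes name lumi and limma without saying what each did. Set against the intensities, the deposited log2 scale flattens at low signal. Its medians differ from log2 intensity by 0.748 for genes of intensity under 64, by 0.445 between 64 and 256 and by −0.0411 over 1024. The exact transformation stays unknown. The deposited log2 table lists 12763 of the 21792 genes, of which 12008 had a detection p of at most 0.01 on at least 1 array, and no gene outside it had one. Its array medians ranged from 7.786 to 7.813. A further 20 columns of per-sample values, the bead standard errors, were not used.

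The intensities were corrected for background with limma 3.58.1 in R 4.3.3. The mean and the spread of the negative controls were inferred from the detection p-values, normexp was applied with an offset of 16, and log2 values were quantile-normalized between arrays. This is limma's neqc procedure with 1 change, made after a first set of results from the default call had been seen. In 683 genes the table averages several probes and combines their detection p-values, so the default call put the control SD at 89.7 to 262 intensity units. Inferring it from the other 21109 genes gave a mean of 50.4 to 74.0 and an SD of 7.48 to 14.3. The default call is reported as an alternative. Genes with a detection p under 0.01 on at least 8 arrays were tested, which left 10488 genes and set 11304 aside. Of the tested genes, 8739 were detected on all 20 arrays.

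Gene names in the table are old. They were updated through a RefSeq gene table of the rat assembly GRCr8, used only for names, since the build behind the array is not given in the sources used here. Of the names, 9918 matched a current symbol, 4746 a synonym and 1545 a gene identifier, while 5583 were kept as they stood. Placeholder names (LOC or RGD numbers) were carried by 9058 genes, 3044 of them tested, and 9 names had been turned into calendar dates.

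Silica and air arrays were compared gene by gene with limma (lmFit, then eBayes with an intensity trend; 2-sided; Benjamini-Hochberg adjusted p under 0.05 over all genes tested). A second count asked in addition for a fold change of at least 1.5 either way. Fold changes are differences of mean log2 intensity, and the offset of 16 draws those of dim genes toward no change. A gene with no detection p under 0.01 on any array of a group was treated as not above background there. Its difference is given as an approximate bound, which carries no sampling error. The 45 gene lists, the naming rule, the comparisons and most alternatives were fixed before the data were examined. The 43 lists with at least 5 measured members were tested with camera (preset correlation 0.01), which compares a list's genes with all others. Camera with an estimated correlation and fry, which asks only whether a list's genes move one way on balance, stand beside it. Each gene was represented by its brightest measurement. The 12 air rats carry identifiers in 3 runs (89 to 92, 105 to 108 and 137 to 140), and the first of these continues the identifiers of the silica rats (81 to 88). The 3 runs were compared with limma's moderated F test. Silica was also compared with each run of 4 air rats alone, since the runs could be batches. These comparisons use the same silica arrays as the main one and are not independent of it. The files name no BeadChip, slide or scan date, so an array batch could not be tested.

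The naming rule took the 12 genes with the largest rise and the 8 with the largest fall among genes with an adjusted p under 0.05, leaving out placeholder names. In each tested list it took up to 4 passing members of smallest p, or the member of smallest p where none passed. It also took 12 genes chosen in advance. Genes named outside it are said to have been chosen after their values were seen.

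Median intensity before normalization ranged from 67.0 to 98.6 between arrays, the number of genes detected per array from 9434 to 10840, and the median number of beads per gene from 40 to 43. The number of arrays limits the precision. Array and rat are the same unit, so the spread between arrays holds the spread between rats. The fitting code was tested on simulated data for 10488 genes with the real group sizes. It recovered 52.9% of 68 genes moved by 0.25 (log2), 95.5% of 66 moved by 0.5 and 100% of 66 moved by 1, with 10 calls among unchanged genes. In the simulated run comparison 74 of 100 moved genes were called, with 3 calls among unchanged ones. Among the simulated lists the 1 moved list and 0 of 20 unmoved lists were called. The simulated genes varied independently of each other, whereas the estimated correlation within real lists reached 0.926. The simulation therefore does not show how often unmoved lists of correlated genes are called.

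Alternatives were other background corrections and normalizations, other detection filters, array weights, other variance models, a Mann-Whitney test, stricter thresholds, other list tests, the replicate number as a block, each run of air rats as the only control, and each array left out in turn. Added after the data were seen were the default neqc call, the identifier run as a block, the array median intensity as a covariate, the controls without rats 89 to 92, and the fit without the 3 arrays of highest median intensity.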

Results

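Lung RNA was measured on 20 arrays, 1 per rat. Crystalline silica, a mineral dust, had been inhaled by 8 rats (identifiers 81 to 88) at 15 mg/m3 for 6 h per day on 5 days, and 12 control rats had breathed air. Lungs of silica rats were taken 16 h after the last exposure. The air rats are listed with the same 6 h per day on 5 days and the same 16 h. The controls fell into 3 runs of 4 consecutive identifiers (89 to 92, 105 to 108 and 137 to 140). Between 9434 and 10840 genes were detected per array. Correlations across genes between pairs of arrays ranged from 0.978 to 0.996, where genes are not independent replicates.

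Silica and air lungs were compared to find which genes respond in the lung right after inhalation of a toxic dust. The largest rise was that of Slc26a4 (array identifier ILMN_1372403), which codes for pendrin, an anion exchanger. Its mean log2 intensity was 10.23 ± 0.29 (SD, n = 8) in silica and 7.32 ± 0.95 (SD, n = 12) in air lungs, a 7.53-fold rise with an adjusted p of 3.15e-07. Cxcl6 (Cxcl5 in the table, ILMN_1369980; log2 fold change 2.81 ± 0.15 SE, adjusted p = 1.14e-11), a chemokine that attracts neutrophils, also rose. It was detected on 1 of 12 air arrays and 8 of 8 silica arrays, and its value ranged from 0.647 to 2.95 between alternatives. Lcn2, an iron-sequestering protein of innate defence, rose 5.56-fold (2.48 ± 0.21), and Mmp12, the macrophage elastase, rose 4.63-fold (2.21 ± 0.29). Among the largest falls were those of Alox15, a lipoxygenase (−1.35 ± 0.12, 2.55-fold lower), Tac1, the precursor of substance P (−1.43 ± 0.10, detected on 1 of 8 silica arrays), and Dlk1, a Notch ligand (−1.37 ± 0.21, detected on 6 of 8). Their order depends on the background correction: with limma's default neqc call they were −1.25, −0.177 and −0.296.

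The 12 largest rises and 8 largest falls leave out genes with placeholder names. Such genes include Cd177 (6.50-fold) and LOC497841 (2.96-fold), which rose, and Sirpb3 (log2 fold change −1.20), which fell. The other genes among the 12 rises were Noxo1 (3.61-fold), an organizer of NADPH oxidase, Rnase9 (3.54-fold), of the ribonuclease A family, and Ch25h (3.06-fold), which makes 25-hydroxycholesterol. The chemokines Ccl2 (3.49-fold), Cxcl1 (3.49-fold), Ccl7 (3.09-fold) and Ccl20 (2.84-fold) and the serine protease Prss30 (2.83-fold, detected on 2 of 12 air arrays) were also among them. Of these 12 genes, 11 were higher on each of the 8 silica arrays than on any air array. Ccl20 was above all air arrays on 1 silica array and missed the threshold against air rats 89 to 92 alone (log2 fold change 1.06, adjusted p = 0.0961). Air rat 90 had a Ccl20 value of 8.53, against 5.85 to 7.04 in the others of that run and a silica mean of 7.95. Against air rats 89 to 92 alone the rise of Slc26a4 was 2.54, that of Cxcl6 2.61, that of Lcn2 2.16 and that of Mmp12 1.93, so Cxcl6 exceeded Slc26a4 there. The remaining genes among the 8 largest falls were Scn3b (−0.78 ± 0.14, and −0.42 against air rats 89 to 92 alone), a sodium channel subunit, Npy (−0.76 ± 0.14), the precursor of neuropeptide Y, and Gp1bb (−0.63 ± 0.11), of the platelet receptor for von Willebrand factor. Ly49s4 (−0.62 ± 0.09), of a family of natural killer cell receptors, and Coro6 (−0.61 ± 0.14), a coronin, completed them, and Coro6 missed the threshold against air rats 89 to 92 alone (−0.41, adjusted p = 0.134).

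**Figure D1:**
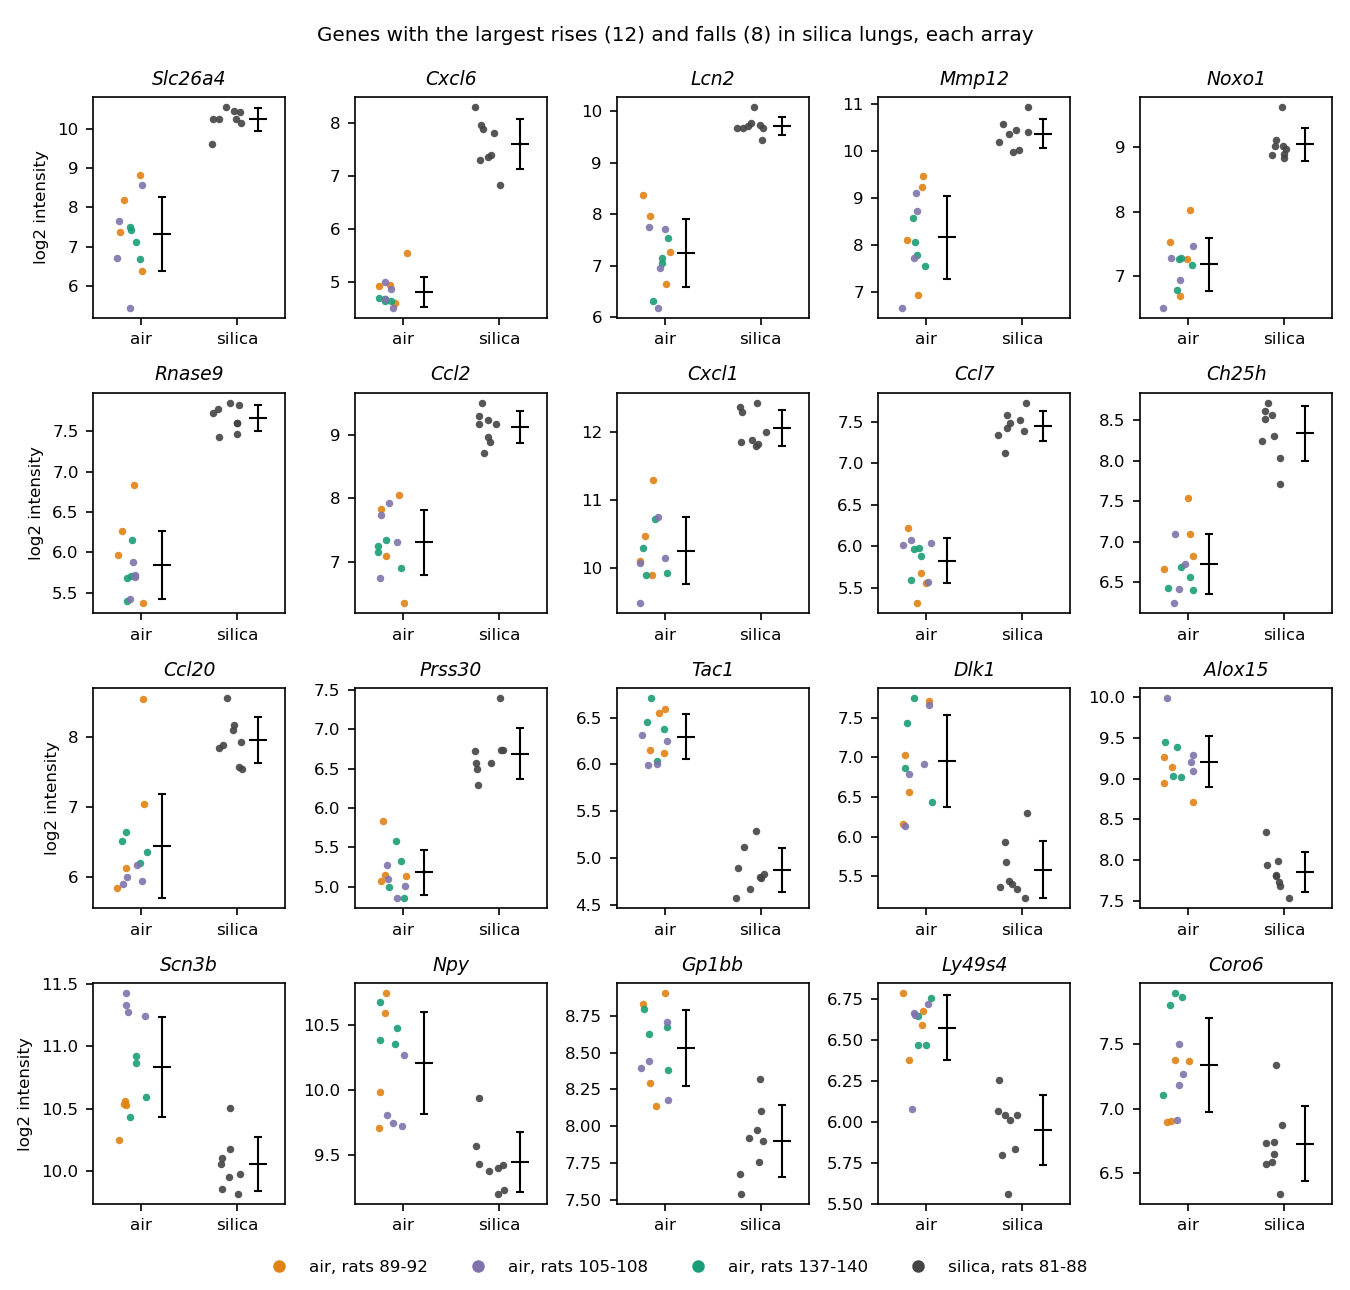
Log2 intensity of the genes with the 12 largest rises and 8 largest falls on each of the 12 air and 8 silica arrays. Genes with placeholder names are left out. Bars give each group's mean and SD, and air arrays are coloured by run of rat identifiers. Silica arrays lie above all air arrays for 11 of the 12 genes that rose.

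Of 10488 genes tested, 2566 (24.5%) changed, of which 1231 rose and 1335 fell. Most changes were small, with a median size of 0.25 on the log2 scale among these genes. A change of at least 1.5-fold was met by 140 genes, 128 higher and 12 lower, and one of at least 2-fold by 31 higher and 4 lower. On every silica array 192 genes lay above, and 78 below, every air array, where chance would give 0.167 genes in all. Against air rats 89 to 92 alone, whose identifiers continue those of the silica rats, 648 genes changed (394 up, 254 down), 92 of them at least 1.5-fold. The count was 1820 against air rats 105 to 108 and 2174 against air rats 137 to 140, and 458 genes changed against each of the 3 runs. All of the 140 genes had the same direction against air rats 89 to 92, and 114 of them passed there.

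Of 26 measured CXC and CC chemokines, which recruit white cells, 17 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.07e-09, and adjusted p = 0.0545 with an estimated correlation). Besides those above, Cx3cl1, of the CX3C class but kept in this list, rose by 0.84 ± 0.06, while Ccl5 (−0.32 ± 0.05) and Ppbp (−0.34 ± 0.09) fell. Of 20 acute phase and innate defence genes, which code for proteins secreted early in inflammation, 12 rose, 0 fell and 8 did not pass (13 up adjusted over the list alone). This list was the 1 called under both settings (camera adjusted p = 7.49e-10, and adjusted p = 0.0268 with an estimated correlation). Chi3l1, a chitinase-like protein, rose by 1.11 ± 0.10, Hp, the haemoglobin carrier haptoglobin, by 1.03 ± 0.09 and Cfb, complement factor B, by 0.41 ± 0.03. Of 21 complement genes, 12 rose and 9 did not pass, among them C1qa (0.43 ± 0.05), C1qb (0.53 ± 0.08) and C1qc (0.51 ± 0.07), the chains of the C1q recognition protein. Camera called the complement list (adjusted p = 3.26e-07, and adjusted p = 0.0545 with an estimated correlation), and adjusted over the list alone 12 rose and 1 fell. Median log2 fold changes were 0.35, 0.36 and 0.22 for chemokine, acute phase and complement lists against all air rats. Against air rats 89 to 92 alone they were 0.27, 0.37 and 0.13, and each list was called there too, with adjusted p values of 1.92e-08, 2.46e-08 and 8.00e-06. With an estimated correlation none of them was called there, the acute phase list included (adjusted p = 0.126, 0.0631 and 0.0631). Of their members 10, 9 and 7 rose there and 1, Ccl5, fell, while Ppbp did not pass (adjusted p = 0.0512) and C1qb rose by 0.35.

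Markers of phagocytes were higher. Of 15 neutrophil markers, 7 rose and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 1.29e-05, and adjusted p = 0.0776 with an estimated correlation). Cd177, a neutrophil surface protein that carries a placeholder name in the table, rose 6.50-fold (2.70 ± 0.21), the decoy interleukin 1 receptor Il1r2 rose by 1.31 ± 0.08 and Trem1, an activating receptor, by 0.59 ± 0.08. Of 17 markers of monocytes and recruited macrophages, 8 rose and 9 did not pass, also adjusted over the list alone (camera adjusted p = 5.30e-05, and adjusted p = 0.0952 with an estimated correlation). They included Arg1, arginase 1 (1.04 ± 0.11), Cd14, a coreceptor for endotoxin (0.65 ± 0.08), and Lgals3, galectin 3 (0.49 ± 0.08). Of 14 alveolar macrophage markers, 7 rose, such as Cd68 (0.92 ± 0.11) and the cholesterol exporter Abcg1 (0.38 ± 0.07), 2 fell, namely Car4 (−0.27 ± 0.04) and Rnase3 (−0.31 ± 0.08), and 5 did not pass (8 up and 2 down adjusted over the list alone). That list had a camera adjusted p of 0.0155, and adjusted p = 0.239 with an estimated correlation. It was not called against air rats 89 to 92 alone (adjusted p = 0.117), whereas the neutrophil and monocyte lists were (2.62e-05 and 8.35e-05). Those calls were lost with an estimated correlation (adjusted p = 0.194 and 0.166). In the comparison with these 4 controls 5 neutrophil, 4 monocyte and 2 alveolar macrophage markers rose and 1, Car4, fell, and Abcg1 (0.26, adjusted p = 0.0991) and Rnase3 (−0.24, adjusted p = 0.158) did not pass. Other lists share 6 of the 15 neutrophil, 7 of the 17 monocyte and 9 of the 14 alveolar macrophage markers. Median log2 fold changes of the 3 lists were 0.26, 0.20 and 0.17 against all air rats and 0.21, 0.17 and 0.12 against air rats 89 to 92 alone.

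The machinery with which cells take up and degrade particles moved the same way. Of 33 lysosomal genes, 21 rose, 0 fell and 12 did not pass (26 up adjusted over the list alone), with a camera adjusted p of 5.47e-12, and adjusted p = 0.0776 with an estimated correlation. Among them were the acid phosphatase Acp2 (0.32 ± 0.03), the proton pump subunit Atp6v1b2 (0.49 ± 0.06), the protease Ctsh (0.39 ± 0.05) and the membrane protein Scarb2 (0.48 ± 0.07). Of 17 particle uptake receptors, 10 rose, 6 did not pass and 1, the oxidized lipoprotein receptor Olr1 (−0.34 ± 0.08), fell (camera adjusted p = 2.25e-05, and adjusted p = 0.106 with an estimated correlation). Adjusted over the list alone 11 rose and 1 fell, and examples are the antibody receptors Fcgr2b (0.72 ± 0.11) and Fcgr2a (0.56 ± 0.10). Of 11 genes of MHC class II antigen presentation, 7 rose, 3 did not pass and 1, the costimulatory receptor Cd40 (−0.27 ± 0.06), fell, with equal counts adjusted over the list alone. Camera called this list (adjusted p = 9.18e-05, and adjusted p = 0.0857 with an estimated correlation), and Ifi30, a lysosomal thiol reductase, rose by 0.54 ± 0.05 and RT1-Db1 by 0.44 ± 0.08. Of 11 genes of NADPH oxidase and the respiratory burst, 5 rose, among them Noxo1, Ncf4 (0.51 ± 0.05), Cyba (0.44 ± 0.06) and Rac2 (0.22 ± 0.05), and 6 did not pass (7 up adjusted over the list alone). The oxidase list had a camera adjusted p of 1.77e-05, and adjusted p = 0.0776 with an estimated correlation. Medians were 0.27, 0.27, 0.31 and 0.22 in the order given, and 0.20, 0.21, 0.21 and 0.21 against air rats 89 to 92 alone. All 4 lists were called there too, with adjusted p values of 3.75e-09, 9.21e-05, 8.17e-05 and 1.93e-04. With an estimated correlation none of them was called there (adjusted p = 0.180, 0.194, 0.180 and 0.180). Of their members 7, 6, 4 and 3 rose there and 0 fell, and of the genes named Olr1, Fcgr2a, Cd40, RT1-Db1 and Rac2 did not pass (adjusted p = 0.0545 to 0.195).

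Oxidative and inflammatory stress responses rose in part. Of 34 antioxidant and Nrf2 target genes, 11 rose, 21 did not pass and 2, Gpx3 (−0.23 ± 0.04) and Sod3 (−0.15 ± 0.05), both extracellular enzymes, fell. This list had a camera adjusted p of 0.00106, adjusted p = 0.106 with an estimated correlation, and 12 up and 3 down adjusted over the list alone. Sod2, the mitochondrial superoxide dismutase, rose by 1.09 ± 0.08, the metal-binding Mt1 by 0.76 ± 0.08, Hmox1, a haem oxygenase, by 0.67 ± 0.10 and Prdx1, a peroxiredoxin, by 0.26 ± 0.04. Of 23 NF-kB targets and regulators, 8 rose, 14 did not pass and Cd40 alone fell, with 9 up and 1 down adjusted over the list alone (camera adjusted p = 0.00152, and adjusted p = 0.117 with an estimated correlation). Tnfaip2 (0.61 ± 0.09) was detected on 1 of 12 air and 7 of 8 silica arrays, and Cd83 rose by 0.31 ± 0.06. Of 14 cytokines and growth factors, 6 rose, 7 did not pass and Tgfb2 (−0.25 ± 0.06) fell, with 7 up and 1 down adjusted over the list alone (camera adjusted p = 0.00457, and adjusted p = 0.153 with an estimated correlation). Il1a and Il1b, the interleukin 1 cytokines, rose by 0.44 ± 0.08 each, and Csf2, a myeloid growth factor detected on 5 of 12 air arrays, by 0.69 ± 0.09. Of 13 inflammasome genes, 6 rose and 7 did not pass, with 6 up and 1 down adjusted over the list alone (camera adjusted p = 0.00939, and adjusted p = 0.153 with an estimated correlation). Casp4 rose by 0.35 ± 0.06, Il18 by 0.40 ± 0.10 and Nek7, detected on 8 of 12 air arrays, by 0.61 ± 0.14. Medians of these 4 lists were 0.08, 0.12, 0.26 and 0.19, and 0.06, 0.13, 0.21 and 0.09 against air rats 89 to 92 alone. There the antioxidant and NF-kB lists were called (0.0143 and 3.15e-04, and adjusted p = 0.267 and 0.199 with an estimated correlation), while the cytokine and inflammasome lists were not (0.0635 and 0.0767). Of the members of the 4 lists 6, 3, 1 (Csf2) and 1 (Casp4) rose there and 1, Gpx3, fell. Il18 (0.22, adjusted p = 0.284), Nek7 (0.29, 0.190) and Tgfb2 (−0.16, 0.105) did not pass there, and neither did Il1a (0.0533), Il1b (0.0708), Cd40 (0.195) and Sod3 (0.228).

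Genes of dividing cells and of sterol synthesis were higher as well. Of 42 cell cycle and mitosis genes, 25 rose, 16 did not pass and 1, the microtubule regulator Stmn1 (−0.15 ± 0.04), fell, with 27 up and 1 down adjusted over the list alone. Camera gave this list its smallest adjusted p, 1.58e-13, and adjusted p = 0.0545 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, rose by 0.88 ± 0.09, Cdkn3, a cell cycle phosphatase, by 0.76 ± 0.09, cyclin B2 (Ccnb2) by 0.62 ± 0.07 and Prc1, a protein of the mitotic spindle, by 0.59 ± 0.05. Of 28 genes of cholesterol and fatty acid synthesis, 9 rose, 0 fell and 19 did not pass, with 13 up adjusted over the list alone (camera adjusted p = 7.27e-06, and adjusted p = 0.0952 with an estimated correlation). Examples are Fdps (0.44 ± 0.05), Mvd (0.33 ± 0.07) and Tm7sf2 (0.67 ± 0.10, detected on 10 of 12 air arrays), all enzymes of the sterol pathway. Of 26 genes of lipid uptake, storage and oxidation, 7 rose and 19 did not pass, also adjusted over the list alone, and Cd36 (0.25 ± 0.05), Lpl (0.25 ± 0.05) and Abca1 (0.28 ± 0.06) were among those 7. That list was called (camera adjusted p = 0.0155, and adjusted p = 0.187 with an estimated correlation), but not against air rats 89 to 92 alone (adjusted p = 0.401). Medians of the 3 lists were 0.25, 0.15 and 0.06, and 0.31, 0.19 and 0.00034 against air rats 89 to 92 alone, where the cell cycle and synthesis lists were called (1.16e-19 and 3.75e-09). Both calls were lost with an estimated correlation (adjusted p = 0.0631 and 0.140). Of the members 17, 7 and 1 (Cd36) rose there and 0 fell, and Abca1 (0.16, adjusted p = 0.231), Lpl (0.19, 0.114) and Stmn1 (−0.11) did not pass.

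Of 21 hypoxia and glycolysis genes, 9 rose, 11 did not pass and Pfkl (−0.22 ± 0.06) fell, with 10 up and 2 down adjusted over the list alone (camera adjusted p = 0.00199, and adjusted p = 0.0776 with an estimated correlation). The hexokinase Hk3 rose by 0.81 ± 0.12, the lactate transporter Slc16a3 by 0.47 ± 0.05 and lactate dehydrogenase A (Ldha) by 0.31 ± 0.04. Of 23 genes of endoplasmic reticulum stress, 10 rose and 13 did not pass, also adjusted over the list alone (camera adjusted p = 5.94e-04, and adjusted p = 0.0857 with an estimated correlation). Among these were Dnajc3 (0.27 ± 0.04), Canx (0.54 ± 0.10) and Xbp1 (0.19 ± 0.04). Of 41 interferon-induced genes, 6 rose, 34 did not pass and Ifitm3 (−0.16 ± 0.05) fell, with equal counts adjusted over the list alone. Cxcl11, detected on 4 of 12 air arrays, rose by 0.66 ± 0.09, Eif2ak2 by 0.41 ± 0.08 and Cxcl9 by 0.30 ± 0.07. The interferon list was called (camera adjusted p = 0.0152, and adjusted p = 0.494 with an estimated correlation), but neither by fry (adjusted p = 0.141) nor against air rats 89 to 92 alone (adjusted p = 0.109) nor without silica rat 82 (adjusted p = 0.169). Medians of the 3 lists were 0.12, 0.12 and 0.07, and 0.06, 0.09 and 0.05 against air rats 89 to 92 alone, where the glycolysis and endoplasmic reticulum lists were called (0.0289 and 0.0237). Both calls were lost with an estimated correlation (adjusted p = 0.222 and 0.238). Of the members 4, 3 and 2 rose there and 1, Pfkl, fell. Canx rose by 0.31, while Cxcl9 (0.19, adjusted p = 0.152), Eif2ak2 (0.0589), Xbp1 (0.0571) and Ifitm3 (0.0909) did not pass.

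Among lung epithelial cells, markers of the surfactant-producing type 2 cells were higher and those of the flat type 1 cells lower. Of 14 type 2 markers, 7 rose, 0 fell and 7 did not pass, with 9 up adjusted over the list alone (camera adjusted p = 9.18e-05, and adjusted p = 0.106 with an estimated correlation). Surfactant protein D (Sftpd) rose by 0.58 ± 0.09, Muc1 by 0.45 ± 0.08, Lamp3 by 0.34 ± 0.06 and the lipid transporter Abca3 by 0.26 ± 0.05. Of 14 type 1 markers, 6 fell, 7 did not pass and Akap5 (0.33 ± 0.10) rose, with 8 down and 1 up adjusted over the list alone (camera adjusted p = 0.00726, and adjusted p = 0.0776 with an estimated correlation). The receptor Ager (−0.20 ± 0.04), the channel protein Clic5 (−0.26 ± 0.04) and Gprc5a (−0.27 ± 0.04) fell, and Ager and Gprc5a were below every air array on 8 of 8 silica arrays. Both lists were called against air rats 89 to 92 alone (0.00270 and 1.93e-04), with medians of 0.14 and −0.19 against 0.22 and −0.15 for all air rats. With an estimated correlation neither was called there (adjusted p = 0.241 and 0.0687). Of the type 2 markers 2 rose there (Lamp3 and Napsa), and Sftpd (0.40, adjusted p = 0.0529), Muc1 (0.36, 0.0533) and Abca3 (0.19, 0.0785) did not pass. Of the type 1 markers 5 fell and 0 rose there (Akap5, adjusted p = 0.162). Of 11 club cell markers, 2 rose (Hp and Cldn10, 0.81 ± 0.09), 3 fell (Cyp4b1, −0.30 ± 0.05, Aldh1a1, −0.17 ± 0.04, and Fmo2, −0.25 ± 0.08) and 6 did not pass, also adjusted over the list alone. That list was not called (adjusted p = 0.882), and its median (−0.04) and mean (0.16) differ in sign. Of 18 ciliated cell markers, Tekt2 (0.26 ± 0.06) rose, Tppp3 (−0.31 ± 0.05) fell and 16 did not pass, also adjusted over the list alone. The ciliated list was not called against all air rats (adjusted p = 0.0797) but was called higher against air rats 89 to 92 alone (adjusted p = 0.0108, and adjusted p = 0.552 with an estimated correlation). It was also called without any 1 of air rats 90 and 137 to 139 and silica rats 81 and 84 (adjusted p = 0.0170 to 0.0494). Fmo2 missed the threshold without silica rat 88 (adjusted p = 0.0562), and Aldh1a1 against air rats 89 to 92 alone (−0.11, adjusted p = 0.156). Other lists share 4 of the type 2 and 7 of the club cell markers.

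Markers of endothelium, stroma, T cells and natural killer cells were lower. Of 16 endothelial markers, 10 fell, 0 rose and 6 did not pass, with 11 down adjusted over the list alone (camera adjusted p = 2.89e-05, and adjusted p = 0.0738 with an estimated correlation). Nos3, the endothelial nitric oxide synthase, fell by 0.43 ± 0.07, Emcn by 0.34 ± 0.06, the receptor Tie1 by 0.33 ± 0.05 and Ramp2 by 0.24 ± 0.04. Of 29 fibroblast and collagen matrix genes, 16 fell, 0 rose and 13 did not pass, with 20 down adjusted over the list alone (camera adjusted p = 3.26e-07, and adjusted p = 0.137 with an estimated correlation). They included the collagens Col4a1 (−0.34 ± 0.06) and Col6a3 (−0.24 ± 0.04) and the matrix proteins Sparc (−0.30 ± 0.05) and Postn (−0.28 ± 0.05). Of 12 smooth muscle and pericyte markers, Myl9 (−0.36 ± 0.06), Smtn (−0.35 ± 0.09), Des (−0.30 ± 0.09) and Cspg4 (−0.28 ± 0.07) fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.0152, and adjusted p = 0.226 with an estimated correlation). Of 12 T cell markers, 9 fell and 3 did not pass, also adjusted over the list alone (camera adjusted p = 2.00e-05, and adjusted p = 0.117 with an estimated correlation), such as Cd3d (−0.43 ± 0.08), Cd3g (−0.40 ± 0.08) and Cd8a (−0.35 ± 0.07). Of 8 natural killer cell markers, 5 fell, namely Prf1 (−0.33 ± 0.05), Ccl5, Klrd1 (−0.32 ± 0.07), Nkg7 (−0.23 ± 0.05) and Ctsw (−0.23 ± 0.08), and 3 did not pass, also adjusted over the list alone (camera adjusted p = 5.30e-04, and adjusted p = 0.124 with an estimated correlation). Of 6 eosinophil markers, Alox15 and Rnase3 fell and 4 did not pass, also adjusted over the list alone (camera adjusted p = 0.0345, and adjusted p = 0.0952 with an estimated correlation). Without air rat 106, silica rat 87 or silica rat 88 the eosinophil list missed the threshold (adjusted p = 0.0522, 0.0574 and 0.0563). Against air rats 89 to 92 alone the endothelial (7.11e-06), fibroblast (3.12e-05), T cell (3.12e-05), natural killer cell (1.93e-04) and eosinophil (0.0316) lists were called, and the smooth muscle list was not (0.239). With an estimated correlation none was called there (adjusted p = 0.0687, 0.194, 0.194, 0.217 and 0.166 for those called). Of the members 5 endothelial, 5 fibroblast, 1 T cell (Cd3e, −0.28), 2 natural killer cell, 1 eosinophil and 0 smooth muscle genes fell there. Cd3d (−0.29, adjusted p = 0.0684), Cd3g (−0.26, 0.104), Cd8a (−0.26, 0.0950), Smtn (−0.14, 0.557), Des (−0.19, 0.397), Myl9 (−0.29, 0.0578) and Cspg4 (−0.30, 0.0557) did not pass there. Neither did Klrd1 (−0.22, 0.198), Nkg7 (−0.24, 0.0811), Ctsw (−0.15, 0.378) and Rnase3 (−0.24, 0.158), and the fall of Nos3 was 0.28. The medians, in the order of the lists, were −0.18, −0.24, −0.16, −0.28, −0.23 and −0.18, and −0.17, −0.17, −0.02, −0.24, −0.23 and −0.17 against air rats 89 to 92 alone.

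**Figure D2:**
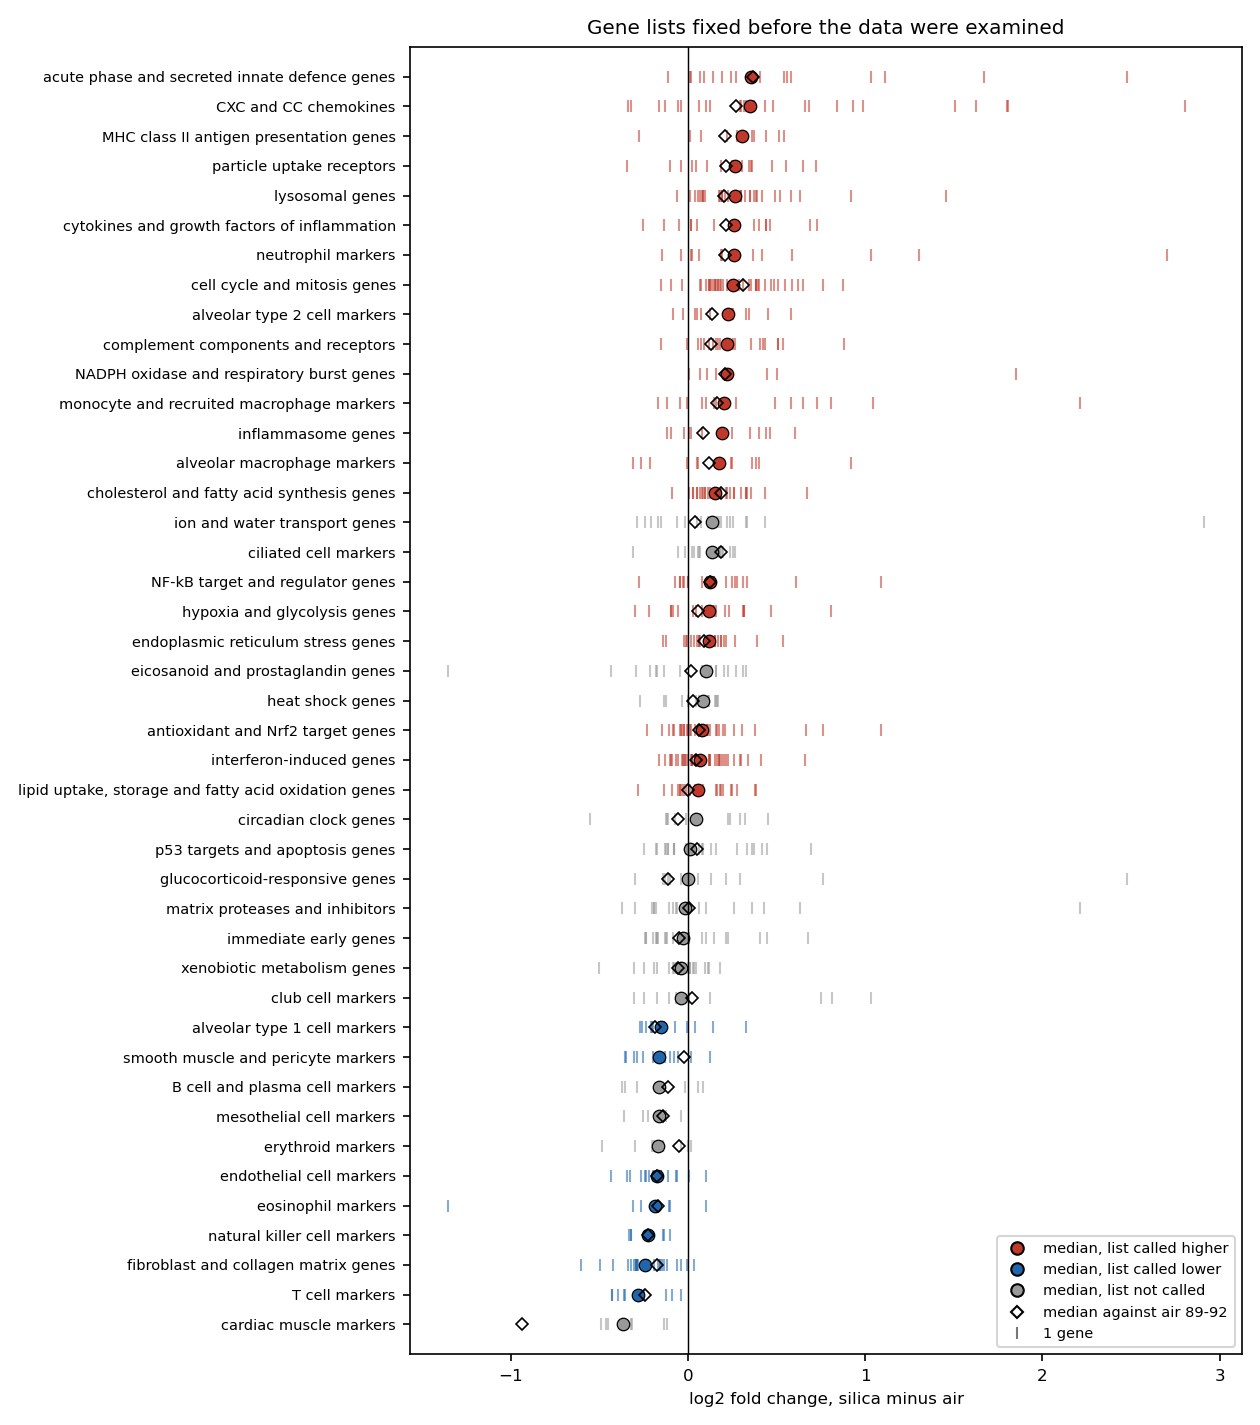
Log2 fold changes, silica minus air, of the members of each gene list (ticks), with the median against all 12 air rats (circle, coloured by camera's call) and against air rats 89 to 92 alone (diamond). Camera called 21 lists higher and 7 lower.

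In all, camera called 28 of 43 lists (21 higher, 7 lower) against all air rats and 23 against air rats 89 to 92 alone, 22 of them in common. With an estimated correlation it called 1 and 0. Fry, which does not compare a list with other genes, called 34 (24 higher, 10 lower), among them the B cell (0.0419), mesothelial (0.0209), erythroid (0.0114), p53 (0.00124), ion transport (0.00471), glucocorticoid (0.0276) and heat shock (0.0252) lists, which camera did not call. The lists not called included B cell markers, of which 2 of 7 fell (Ms4a1, −0.37 ± 0.10, and Cd79b, −0.28 ± 0.10; 3 adjusted over the list alone; adjusted p = 0.191), and mesothelial markers, of which 2 of 7 fell (Krt19, −0.16 ± 0.04, and Krt8, −0.12 ± 0.04, also adjusted over the list alone; adjusted p = 0.114). Of 8 erythroid markers, 2 fell, among them Alas2 (−0.48 ± 0.15), with 4 down adjusted over the list alone (adjusted p = 0.126). Of 9 cardiac muscle markers, 0 passed, also adjusted over the list alone (adjusted p = 0.473), and Pln had the smallest p (−0.45 ± 0.19). Without silica rat 88, Pln passed (adjusted p = 0.0285). The median of −0.37 went with a mean over the list of 5.11 to 9.06 between air arrays and 4.96 to 8.56 between silica arrays. With air rats 89 to 92 as the only controls, 0 members of these 4 lists passed, and Ms4a1 (−0.12, adjusted p = 0.586) and Cd79b (−0.11, 0.678) kept little of their size. Cd79b also missed the threshold when any 1 of air rats 91, 106 and 137 to 140 or silica rats 82, 83 and 85 to 88 was left out (adjusted p = 0.0515 to 0.0876). So did Krt8 without air rat 138 or 140 or silica rat 81, 83, 85 or 86 (0.0520 to 0.0782).

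Sizes of some lists and genes depend on the background correction. With limma's default neqc call, an alternative added after the data were seen, medians of called lists that shrank by over 1.5 times were 0.19 for chemokines, 0.12 for complement, 0.04 for neutrophil, 0.10 for alveolar macrophage and −0.09 for T cell markers. They were 0.11 for NADPH oxidase, 0.03 for NF-kB, 0.06 for cytokine, 0.03 for inflammasome, 0.05 for cell cycle, 0.07 for sterol and fatty acid synthesis, 0.07 for endoplasmic reticulum stress and 0.02 for interferon-induced genes. These lists were still called, while the eosinophil list, with a median of −0.03, was not (adjusted p = 0.0539). Of lists not called, the medians were −0.14 for cardiac muscle and 0.02 for eicosanoid genes. Among genes of the naming rule, Csf2 was 0.08, Tnfaip2 0.06, Cxcl11 0.07, Nek7 0.08, Eif2ak2 0.07, Tm7sf2 0.14, Nr4a3 0.04, Ly49s4 −0.11, Alas2 −0.10, Mmp11 −0.09, Cd40 −0.09 and Pln −0.09 under that call. Rnase9 was 0.52, Ccl7 0.43, Ccl20 0.56, Prss30 0.24, Ch25h 0.85, Coro6 −0.22, Fcgr2b 0.23, Ms4a1 −0.12, Cd79b −0.13, Cdkn3 0.29, Rrm2 0.44 and Spp1 0.26. Il1r2 was 0.75, Trem1 0.31, Ncf4 0.30, Canx 0.31, Rgs1 0.37 and Myl9 −0.22.

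Several lists held changes in both directions. Of 21 matrix proteases and inhibitors, Mmp12, Slpi (0.36 ± 0.06), Ctsk (0.63 ± 0.19) and Timp3 (0.43 ± 0.13) rose, and Mmp11 (−0.37 ± 0.07), Plat (−0.19 ± 0.04), Adamts9 (−0.30 ± 0.08) and Timp2 (−0.18 ± 0.05) fell. That list had 4 up and 5 down adjusted over the list alone and an adjusted p of 0.963, with a median of −0.02, a mean of 0.11 and a test direction downward. Of 18 eicosanoid genes, 5 rose, among them Lta4h (0.20 ± 0.04), Alox5ap (0.31 ± 0.06) and Alox5 (0.23 ± 0.07) of the leukotriene pathway, Tbxas1 (0.27 ± 0.06) and Pla2g1b (0.33 ± 0.08). The 5 that fell were Alox15, Pla2g2a (−0.43 ± 0.11), Hpgd (−0.21 ± 0.06), Alox12 (−0.18 ± 0.06) and Ltc4s (−0.29 ± 0.09), with 6 up and 5 down adjusted over the list alone, an adjusted p of 0.596, a median of 0.10 and a mean of −0.05. Of 20 ion and water transport genes, 7 rose, Slc26a4 foremost, and 3 fell, among them the water channels Aqp1 (−0.24 ± 0.05) and Aqp5 (−0.21 ± 0.06) (7 up and 5 down adjusted over the list alone; adjusted p = 0.0836, or 0.0473 without silica rat 82). Of 27 immediate early genes, Myc (0.40 ± 0.06), Nr4a3 (0.44 ± 0.06, detected on 10 of 12 air arrays), Rgs1 (0.68 ± 0.17) and Egr2 (0.22 ± 0.08) rose. Rgs2 (−0.24 ± 0.07), Klf4 (−0.24 ± 0.07), Dusp6 (−0.18 ± 0.05) and Ccn2 (−0.17 ± 0.06) fell, with 4 up and 5 down adjusted over the list alone, an adjusted p of 0.963, a median of −0.03, a mean of 0.0039 and a test direction upward. Of 27 p53 targets and apoptosis genes, 8 rose (3 against air rats 89 to 92 alone), such as Bcl2a1 (0.69 ± 0.09), and Phlda3 (−0.17 ± 0.04) and Fas (−0.25 ± 0.07) fell (8 up and 3 down adjusted over the list alone; adjusted p = 0.135). Timp3, against air rats 89 to 92 alone, differed by 0.01 (adjusted p = 0.965), and Ctsk by 0.30 (adjusted p = 0.482). Of the genes named in these 5 lists, Mmp12, Slpi, Plat, Adamts9, Lta4h, Alox15, Slc26a4, Aqp1, Myc, Nr4a3 and Bcl2a1 passed there, and the others did not. Among those, Alox5ap (0.16), Pla2g1b (0.16), Alox12 (−0.08), Rgs2 (−0.15) and Dusp6 (−0.10) differed by over 1.5 times less than against all air rats.

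Of 26 xenobiotic metabolism genes, the esterase Ces1d (0.18 ± 0.04) rose and Cyp4b1, Aldh1a1, Fmo2 and Cyp1a1 (−0.50 ± 0.17) fell, also adjusted over the list alone (adjusted p = 0.473). Of 13 circadian clock genes, Bhlhe40 (0.32 ± 0.08) and Bhlhe41 (0.45 ± 0.12) rose and Nr1d1 (−0.55 ± 0.15) fell, also adjusted over the list alone (adjusted p = 0.473). None of the 3 passed against air rats 89 to 92 alone, where Bhlhe40 differed by 0.13 (adjusted p = 0.494), Bhlhe41 by 0.25 (0.195) and Nr1d1 by −0.58 (0.158). Of 15 glucocorticoid-responsive genes, Lcn2, Mt1 and Nfkbia (0.22 ± 0.06) rose, also adjusted over the list alone (adjusted p = 0.178). These 3 also stand in lists of innate defence, antioxidant or NF-kB genes, and the list's median (−0.0018) and mean (0.21) differ in sign. The glucocorticoid-responsive genes were called higher against air rats 105 to 108 alone (median 0.21, adjusted p = 0.00982) and without air rats 89 to 92 (median 0.12, adjusted p = 0.0236, an alternative added after the data were seen). Their median was −0.11 against air rats 89 to 92 alone, where the list was not called. Both calls used the preset correlation. With an estimated correlation the glucocorticoid list was not called against all air rats (adjusted p = 0.479), and that setting was not run for the controls of these calls. Of 14 heat shock genes, Hspd1 (0.17 ± 0.03), Dnaja1 (0.16 ± 0.04), Hspa5 (0.15 ± 0.04) and Hspe1 (0.16 ± 0.06) rose and Cryab (−0.27 ± 0.05) fell, with 6 up and 2 down adjusted over the list alone (adjusted p = 0.135). Mast cell markers (4 measured, of which Hdc, 0.24 ± 0.06, rose and Gata2, −0.20 ± 0.06, fell) and goblet cell markers (3 measured, of which Muc1 rose) were too few to test, and their counts were the same adjusted over the list alone. Of the other genes with a value here, Ces1d, Cyp1a1 (−0.30), Nfkbia, Dnaja1, Hspa5, Hspe1 (0.07) and Gata2 did not pass against air rats 89 to 92 alone (adjusted p = 0.0707 to 0.666). The genes named as the few members of a list that passed one way, outside the naming rule, were chosen after their values were seen.

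Of the 12 genes chosen in advance, Slc26a4, Lcn2, Cxcl1, Ccl2, Sod2, Hmox1, Il1b and Arg1 rose, Il1b not against air rats 89 to 92 alone (adjusted p = 0.0708). The log2 level of Scgb1a1, the club cell secretory protein, was 14.28 ± 0.09 (SD) in silica and 14.27 ± 0.09 in air lungs (adjusted p = 0.942), and that of surfactant protein C (Sftpc) 14.10 ± 0.08 and 14.06 ± 0.10 (adjusted p = 0.560). Both lie near the top of the array's range. Spp1, osteopontin, had a log2 fold change of 0.73 ± 0.32 (adjusted p = 0.102, or 0.0346 without air rat 91), and Tnf was not above background on any array. Some genes were above background in 1 group only, chosen here after their values were seen. By approximate bounds, Dmkn was 2.24-fold, LOC679271 2.47-fold and Stra6l 1.82-fold higher in silica lungs. Sirpb3 was 2.09-fold, Sytl5 1.34-fold and Cadm1 1.19-fold lower by such bounds. Sampling error is not included, and for LOC679271 the bound equals the measured rise. The files name no slide or scan date, so a batch of arrays that follows the groups could not be tested for. The pooled counts rest on controls that differed among themselves.

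The 3 runs of air rats were compared to see whether the controls form 1 population. Adgrl1, an adhesion receptor, was lower in air rats 89 to 92 (9.03 ± 0.06, SD, n = 4) than in air rats 105 to 108 (9.53 ± 0.03) and 137 to 140 (9.60 ± 0.12), with an adjusted p of 0.00613. Scn3b was highest in air rats 105 to 108 (11.32 ± 0.08, against 10.47 ± 0.15 in 89 to 92 and 10.71 ± 0.23 in 137 to 140), and so were elastin (Eln, 12.21 ± 0.15 against 11.49 ± 0.21 and 11.50 ± 0.17) and the collagen Col1a1 (10.62 ± 0.08 against 9.98 ± 0.28 and 10.07 ± 0.10). Timp3, an inhibitor of matrix proteases, ran from 8.03 ± 0.18 in 89 to 92 through 7.60 ± 0.24 to 7.20 ± 0.14 in 137 to 140. Copz1, a subunit of the vesicle coat COPI, was lowest in air rats 137 to 140 (8.21 ± 0.11, against 8.76 ± 0.12 and 8.66 ± 0.06). These genes were picked after their values were seen.

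By limma's moderated F test, 17 of 10488 genes differed among the runs at an adjusted p under 0.05, while 1225 had an unadjusted p under 0.05. Between pairs of runs 8 genes differed for 89 to 92 and 105 to 108, 16 for 89 to 92 and 137 to 140, and 3 for 105 to 108 and 137 to 140. The F test count was 44 without air rat 92, and between 5 and 11 without any 1 of air rats 89, 90, 105, 107 and 137 to 140. Each array was also placed on a scale from the mean of air arrays (0) to the mean of silica arrays (1), over all genes tested and with that array left out of the means. Air rats 89 to 92 scored 0.325 ± 0.164 (SD, n = 4) and the other air rats −0.0422 ± 0.0971 (n = 8), a difference of 0.367 (exact 2-sided permutation test over 495 splits, p = 0.00202). The silica rats scored 0.890 ± 0.125. Since each score leans on the other air arrays, the runs were also compared along a difference between silica and the run not compared. On that scale, air rats 89 to 92 lay 0.291 above 105 to 108 (exact p = 0.0571 over 70 splits) and 0.310 above 137 to 140 (exact p = 0.0286), while 105 to 108 and 137 to 140 differed by −0.0374 (exact p = 0.543). Unadjusted for these 3 comparisons, 1 of them passed.

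**Figure D3:**
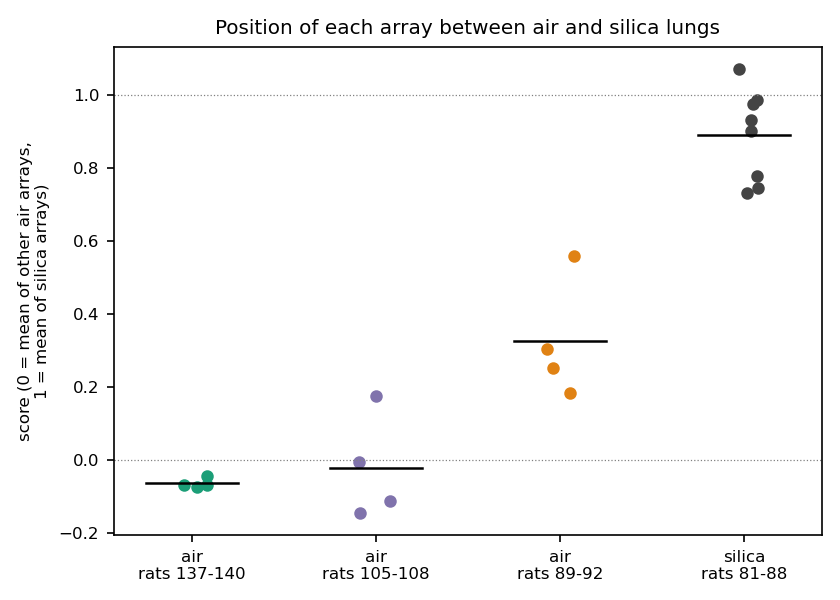
Score of each array between the mean of air arrays (0) and the mean of silica arrays (1), by run of rat identifiers, with each run's mean as a line. Air rats 89 to 92 average 0.325 and silica rats 0.890.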

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

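Of the tests in this part, those of the fallen cell marker lists, of the glucocorticoid-responsive genes, and of chance and of mixed-in silica RNA for the score of air rats 89 to 92 were chosen only after the result was seen.

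Random splits of single arrays did not reach the gene counts of silica against air. Of 100 splits of the 20 arrays into 8 and 12, 1 (the real one) gave as many as 2566 changed genes, with 642 the highest of the others, and 1 gave as many as 140 genes changed at least 1.5-fold, with 26 the highest of the others. For the gene lists 2 of 100 splits gave as many as 28. The other split gave 29, so the list count was not beyond every other split. The group of 8 in that split held 1 silica array and 3 of air rats 89 to 92, and why it gave as many lists was not tested. For the 3 runs of air rats 1 of 100 splits gave as many as 17 genes, with 1 gene the highest of the others. The splits of the 20 arrays treat single rats as interchangeable. The silica rats are 1 run of identifiers and the air runs differed, so a difference between runs is not excluded as a source of the silica counts.

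The air rats 89 to 92 lay nearer the silica rats than the other air rats did, by 0.367 of the distance between air and silica means (exact p = 0.00202, the smallest that 495 splits can give). A linear effect of the median signal of each array does not account for it, since the difference was 0.337 with that signal regressed out (exact p = 0.00202). Other effects of array background were not tested. Silica RNA mixed into these 4 samples is argued against by the cell cycle genes, though most other lists go with it. The mean of the cell cycle genes lay −0.0660 ± 0.0669 (SE) from that of the other air rats, where the mixed share would put it at 0.104. Of the other lists called higher in silica lungs, those of cholesterol and fatty acid synthesis (−0.0689) and NF-kB genes (−0.0181) were also lower in these 4 rats. The rest were higher, such as acute phase (0.183) and lysosomal genes (0.139), as mixing would give. Of the lists called lower in silica lungs, type 1 (0.0615), natural killer (0.0157) and endothelial markers (0.00417) were not lower in these 4 rats, unlike what mixing would give. Smooth muscle (−0.129), fibroblast (−0.124), T cell (−0.0815) and eosinophil markers (−0.0624) were lower. A candidate explanation left open is a difference in handling, housing or date between the runs, which the labels do not give, and no biological explanation was tested.

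Lists of resident cell markers (type 1, endothelial, fibroblast, smooth muscle, T and natural killer cells) fell in silica lungs. Dilution of resident cells by arriving ones, acting alone, would lower the markers of every resident type. The mean of the type 2 cell markers was 0.203 ± 0.0400 (SE) higher, so dilution alone does not give the whole pattern. A separate rise of type 2 markers could hide dilution, so dilution stays possible for the lists that fell. Scaling between arrays was examined relative to the median of all genes. The list and normalization nearest to no change (type 1 markers, default neqc call) had a mean of −0.0907 ± 0.0259. Camera had already chosen these lists for lying below other genes in the same data, so this outcome was largely fixed in advance. It is no independent evidence against scaling. An earlier form of that test, on medians, had not decided it. A lower share of these cells and a lower expression in each could not be separated in whole lung RNA, and an effect of silica on either stays open.

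Glucocorticoid-responsive genes were higher in air rats 89 to 92 than in the other air rats by 0.240 on average (exact p adjusted over 43 lists = 0.0434), and so were the circadian clock genes by 0.128 (adjusted exact p = 0.0434). Before adjustment both lists had the smallest exact p that 495 splits can give (0.00202). The adjusted value passed only because both lists tied there. Fkbp5, a glucocorticoid-induced chaperone, averaged 10.40 ± 0.76 (SD) in air rats 89 to 92, 9.46 ± 0.24 in other air rats and 9.73 ± 0.29 in silica rats, with 3 of the 4 rats above all other air rats. Other members differed: Sgk1 was lower in air rats 89 to 92 (−0.0961, exact p = 0.0444), and Klf9 (0.234, exact p = 0.0667) and Dusp1 (0.0250, exact p = 0.806) did not pass. The clock genes Dbp (−0.15 ± 0.26 SE), Nr1d1 (0.0384 ± 0.232), Per2 (0.0652 ± 0.188) and Bmal1 (−0.0457 ± 0.103) differed by less than Per1 (0.83 ± 0.36), which glucocorticoids also induce. Dbp was dim, at 5.35 in air rats 89 to 92 and 5.50 in other air rats, where the offset draws differences toward no change. Time of day at sacrifice still cannot be told apart from another cause, since the spread between 4 rats keeps the gap between Dbp and Per1 within 2 standard errors, and no biological explanation was tested.

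Single arrays stood apart from the others of their group in 9 of 162 values over the silica arrays and 5 of 54 over the runs of air arrays, where chance gives about 1 in 20. On the log2 scale, silica rat 82 was low for Slc26a4 (9.603). Other silica rats were high, namely 84 for Noxo1 (9.615), 88 for Prss30 (7.394), 87 for Cd14 (10.45) and 83 for Abcg1 (12.53) and Spp1 (8.831). Silica rat 86 had the highest median signal of its group (98.62) and the lowest number of detected genes (9480), and lay apart on the second principal component (−21.53). Among air rats, 138 was low for Adgrl1 (9.430), 91 low for Scn3b (10.25), 107 high for Ighv (7.527), and 105 and 139 high for LOC317070 (8.732 and 8.986).

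Some genes left out of the test, detected on too few arrays, were detected on at least 5 silica arrays and on 0 of 12 air arrays. These were C4bpb on 7 of 8 silica arrays, Ccl22, Gucy2g, Oscar and Spink2 on 6 each, and Dsg2 and LOC497783 on 5 each. All were dim, with mean log2 intensities of 4.763 to 5.049 in air and 4.936 to 5.531 in silica lungs. By limma with no detection filter, Dsg2 did not pass (adjusted p = 0.0552), while the others did.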

How the results depend on the processing

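The alternatives called added here, and the tests on them, were chosen only after the results were seen. Under the alternatives fixed beforehand and those added, none of the named genes or tested lists that were called changed direction. Under those fixed beforehand, 5202 values of named genes kept their side of the threshold, 119 no longer passed and 3 newly passed, and for lists the numbers were 1391, 44 and 25. Under added alternatives they were 733, 51 and 1 for genes and 204, 8 and 3 for lists.

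The 2566 changed genes became 1539 with the replicate number as a block, which takes up degrees of freedom for pairs that the data do not show, 648 against air rats 89 to 92 alone, and 768 with the run as a block (added), which compares silica with the same 4 rats. The cause of the fall to 648 was not tested, and the other runs of 4 controls gave 1820 and 2174. An adjusted p under 0.01 left 1441. The other alternatives gave 1820 to 3076, among them 2325 by a Mann-Whitney test and 2149 with no detection filter.

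The 140 genes changed at least 1.5-fold became 86 with no background correction, 81 with normexp and an offset of 50, and 64 in the deposited values, all of which draw dim genes toward no change. They became 76 with the default neqc call (added), 92 against air rats 89 to 92 alone, 253 against air rats 137 to 140 alone and 212 without air rats 89 to 92 (added), and 35 at 2-fold. The cause was not tested for these. Some genes moved far with the default neqc call, where Cxcl6 went from 2.81 to 0.647, Rnase9 from 1.82 to 0.522, Ccl7 from 1.63 to 0.425, Prss30 from 1.503 to 0.236, Tac1 from −1.43 to −0.177 and Dlk1 from −1.37 to −0.296, so the order of the largest changes depends on the background correction.

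The 28 lists became 1 with an estimated correlation, which lay above the preset 0.01 for most lists. The cause was not tested. The eosinophil list lost its call too (adjusted p = 0.0952), though its estimated correlation was −0.0091. The 17 genes that differed among the air runs became 10 with the default neqc call (added) and 11 with no detection filter, and the cause was not tested. Medians of lists moved too. With the default neqc call the neutrophil median went from 0.26 to 0.0393, the T cell median from −0.28 to −0.0893 and the cell cycle median from 0.25 to 0.0492, and in the deposited values they were 0.105, −0.170 and 0.113. With no detection filter the cytokine median was 0.0453 and the inflammasome median 0.0490. Against air rats 105 to 108 alone the fibroblast median was −0.415, and against air rats 137 to 140 alone −0.132.

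Leaving out 1 array at a time gave 2182 to 2763 changed genes, 126 to 155 at least 1.5-fold and 27 to 29 lists. The run comparison ranged from 5 genes, without air rat 137 or 140, to 44, without air rat 92. It gave 7 without air rat 89, 9 without 90, 11 without 107 and 8 without 105, 138 or 139. An alternative with the array batch was not run, since the files name none. Signal over background limits dim genes, whose fold changes are drawn toward no change.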

Other observations

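The genes named in this part were picked only after their values were seen, and no other test was chosen that way here.

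Several genes with placeholder names in the table changed at least 2-fold and so fell outside the naming rule. Rab7b, a GTPase of late endosomes and lysosomes, rose 2.41-fold (log2 fold change 1.27 ± 0.11 SE, adjusted p = 8.93e-09). LOC497841, which has no other name, rose 2.96-fold, LOC501015 2.58-fold and LOC497762 2.19-fold.

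Replicate numbers did not pair silica with air arrays. With group means removed, the correlations across genes of arrays with equal numbers ran from −0.228 to 0.163 over 8 pairs, and for 0 of 8 silica arrays was the air array of the same number the closest. The first principal component held 26.3% and the next 14.6% of the variance between arrays.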
